A study of Mus musculus with 6 samples.

How the data were processed

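Expression was measured on 6 arrays, each hybridised with RNA of 1 mouse, 3 labelled Aire WT and 3 labelled Aire KO. Per the labels' protocols, thymi were digested with collagenase and dispase, cells were sorted into Trizol, RNA was amplified in 2 rounds, and biotinylated cRNA was made by the array maker's standard method. The annotation used for the probe sets is that of an Affymetrix Mouse Gene 1.0 ST array, on which a probe set summarises probes along a whole transcript. The values the authors deposited are probe set intensities made by RMA, per the submitters' processing notes. RMA subtracts background, forces all arrays to 1 distribution and summarises probes by median polish. The version, the genome build and whether other arrays were normalized in the same run are not given in the sources used here. The deposited intensities are on the linear scale, with array medians between 92.9 and 98.2. Quantile normalization hides any change in total RNA per cell, and background compresses the fold of dim genes. RMA values carry no detection call, so signal over background could not be tested per probe set.

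The deposited table holds 35512 probe sets and 6 columns of values, all matched to a sample by name. In the platform annotation 21789 probe sets have 1 gene symbol, 1621 have several and 12102 have none. A probe set with several symbols was given no name. Entrez identifiers of 21698 of the 1-symbol probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names and gene order, and its coordinates are not printed because the files name no build. Of all rows, 476 hold the same values as an earlier row, and no such pair is among the tested genes. No pair of arrays shared more than 50 identical intensities, so none was a repeat of another.

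Intensities were log2 transformed with a pseudocount of 0. Each of 19938 genes was represented by its 1-symbol probe set of highest mean. A gene was tested if its log2 value lay above the 40th percentile of all values, 5.97, in at least 3 of the 6 arrays, which left 13925 genes and set 6013 aside as dim. Genotype was the only factor in the model. The test was limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and errors printed as SE come from that fit. Figures were drawn with matplotlib 3.10.9. Labels give no scan date or other batch, so none could be modelled.

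Gene lists for cell types and processes were written from general knowledge before the data were examined, as were the test, the filter, the rule for named genes and most alternatives. The 26 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 26, and again with the correlation estimated. The fry test of limma, which does not compare a list with the other genes, was run beside camera, and its p-values are unadjusted. Lists overlap: Csn1s1 and Csn1s2a stand in 2 of them, as do Fgb, Apob, Krt10, Ccl20, Ccl9 and Cxcl9, and others such as Icosl and Ccl25. Listed symbols that had changed were updated (Spt1 to Mucl2, Muc10 to Prol1, March1 to Marchf1). Counts adjusted over a list alone come from the same p-values, adjusted within the list. Named genes are Aire, the 12 largest falls and 12 largest rises among called genes whose groups do not overlap, and up to 4 called members of each list in order of adjusted p. Other members in the text were chosen after their values were seen.

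Adjacent pairs of tested genes were counted in the gene order and compared with 10000 permutations of the calls. Windows of 15 genes were compared with 200 permutations. The spread between mice was compared as the median log2 ratio of SDs, over all 10 splits of the arrays into 3 and 3. The test was checked on simulated arrays with 13925 genes, 200 of them changed: it recovered 62% of those changed by 0.5 on the log2 scale, 94% at 1 and 100% at 2 and 3, with 12 unchanged genes among 190 calls, and called 0 genes on arrays with no change. The simulated genes varied independently, and far fewer changed than the 26.1% called in the data, so these rates may not carry over.

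Alternatives covered the filter (none, or the 60th percentile), another quantile normalization, centring on the median, an offset of 32, the probe set rule, the variance model, array weights, the replicate number as a block, treat at a log2 change of 0.5, the X and Y chromosomes left out, and each array left out in turn. Fits without 1 array were first run with the filter applied again to the 5 arrays left. After those values had been seen, the fits were also run on the genes tested with all 6 arrays, and both are reported. Leaving out probe sets by the suffix of their name was not run, since the names carry none, and the planned comparison of control probe sets at both ends of transcripts was not run, since no probe set is named as such a control.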

Results

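The series measured gene expression in thymic medullary epithelial cells, the stromal cells of the thymus that display proteins of other organs to developing T cells. The cells were sorted as CD45-negative, Ly51-intermediate and MHC class II high from mice of 4 to 6 weeks on a (B6xNOD)F1 background, 3 labelled Aire wild type (WT) and 3 labelled Aire knockout (KO). Aire is a transcriptional regulator expressed in these cells. Each mouse gave its own sample, so the errors below are spreads between mice, and RNA from each was amplified in 2 rounds before hybridisation to a whole-transcript mouse array. Median intensities ran from 92.9 to 98.2 on the 6 arrays, with maxima between 27574 and 29965. Pearson correlations of log2 intensity, which are across probe sets and not across replicates, were 0.990 to 0.993 within WT, 0.991 to 0.993 within KO and 0.976 to 0.985 between the groups. Values below are log2 intensities, the difference is the KO-labelled mean minus the WT mean, and the number of arrays limits the precision.

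Aire itself, measured by probe set 10370397, gave a higher signal on the arrays labelled KO. Its log2 intensity was 11.97 ± 0.04 in the 3 WT mice and 12.41 ± 0.02 in the 3 mice labelled KO (SD). The difference was 0.44 (SE 0.08, n = 3 per group, limma adjusted p = 0.0017). The labels do not say which part of the gene was deleted, and the probe set summarises the whole transcript, so this signal does not check the genotype labels. The groups are therefore called by their labels throughout. Genes next to Aire were also higher: Dnmt3l, a cofactor of DNA methylation in germ cells and the nearest tested gene on one side, rose 4.07-fold from 8.40 ± 0.13 to 10.43 ± 0.08 (SD, n = 3). Icosl, a costimulatory ligand, rose by 0.43 on the log2 scale, Gatd3a by 0.38 and, on the other side of Aire, Pfkl by 0.50 and Lrrc3 by 0.26. Of the 8 tested genes nearest to Aire, 5 rose, a count that 0.54% of the windows around other genes matched. Of 23 tested genes on a longer list of neighbours, 6 rose and 0 fell by limma (6 and 0 adjusted over the list alone), and 17 did not pass. The median of that list was 0.13, which did not pass camera (adjusted p = 0.056, and adjusted p = 0.28 with an estimated correlation). It passed without WT replicate 2 (adjusted p = 0.044), WT replicate 3 (0.040), KO replicate 1 (0.048) or KO replicate 3 (0.048). With all arrays it passed with the stricter intensity filter (0.041), an offset of 32 (0.042), the mean of a gene's probe sets (0.044), trended, robust variances (0.042) and array weights (0.048).

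**Figure D1:**
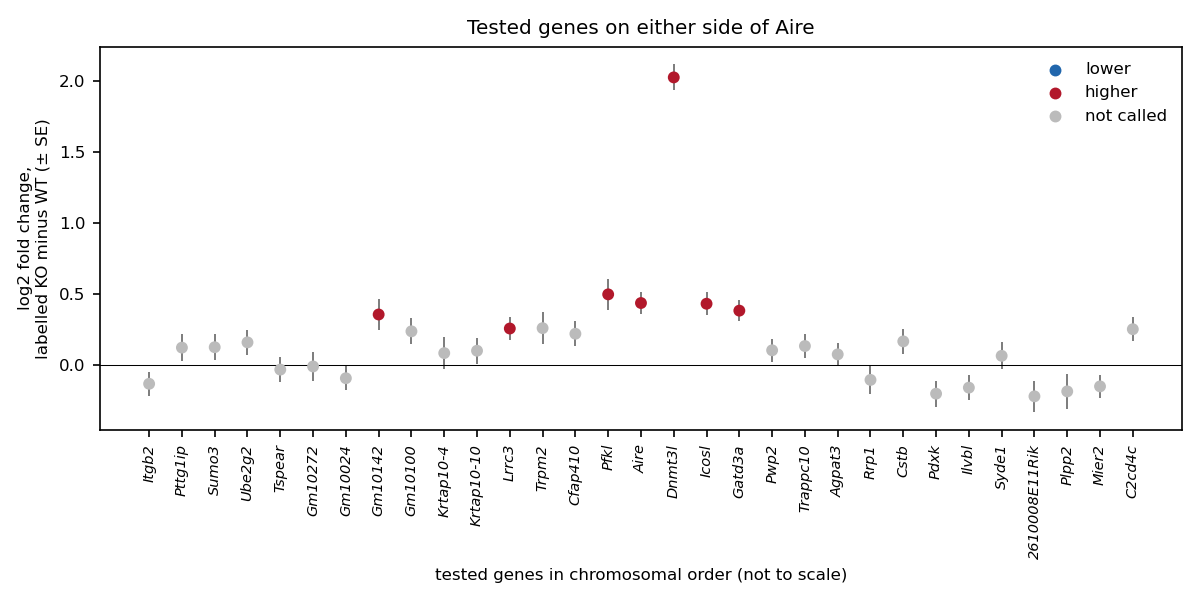
Log2 fold change (labelled KO minus WT, vertical axis) of Aire and the 15 nearest tested genes on each side, in chromosomal order and not to scale, with SE bars and n = 3 arrays per group. Dnmt3l stands at 2.02, and Pfkl, Aire, Icosl and Gatd3a lie between 0.38 and 0.50.

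The comparison of the genotypes asks which genes depend on Aire in these cells. Genes of several organs stood among the largest falls in the mice labelled KO, though the breadth over organs was not tested. Akr1c18 (probe set 10407435), a progesterone-inactivating enzyme, fell 21.9-fold from 9.59 ± 0.25 to 5.13 ± 0.22 (SD, n = 3 per group, limma adjusted p = 3.5e-09). The granulocyte antigen Ly6g fell 15-fold, Gatm of creatine synthesis 13.6-fold, neurotensin (Nts) 12.9-fold, Gpr50 12.5-fold and the enamel protein gene Amtn 12.2-fold. Carbonic anhydrase Car1 (11.3-fold), hepatic Cyp1a2 (9.80-fold), the milk casein Csn1s2a (9.34-fold), the odorant-binding protein gene Obp2a (9.21-fold), the pepsinogen gene Pgc (9.12-fold) and calretinin (Calb2, 8.98-fold) completed the 12 largest falls. Their log2 changes lay between -4.45 and -3.17, and for all but Pgc every array labelled KO lay under the intensity filter, so those folds are limited by the background.

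The rises were smaller. Tafa1 (probe set 10540233), which encodes a secreted neuronal protein, rose 5.83-fold from 7.65 ± 0.10 to 10.19 ± 0.05 (SD, n = 3 per group, limma adjusted p = 6.4e-09). Uts2b rose 4.74-fold, the inhibitory T cell receptor gene Ctla4 4.62-fold, Dnmt3l 4.07-fold, Serpina9 3.99-fold and the lymphocyte receptor gene Ly9 3.96-fold. Olfr1136 (3.53-fold), B3galt5 (3.44-fold), Ostn (3.32-fold), I830077J02Rik (3.20-fold), the synapsin gene Syn2 (3.03-fold) and the cannabinoid receptor gene Cnr2 (2.90-fold) completed the 12 largest rises. Olfr1136 belongs to a large family of similar receptors and may share probe sequence with them, which was not tested here. The log2 rises of the 12 lay between 1.54 and 2.54.

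**Figure D2:**
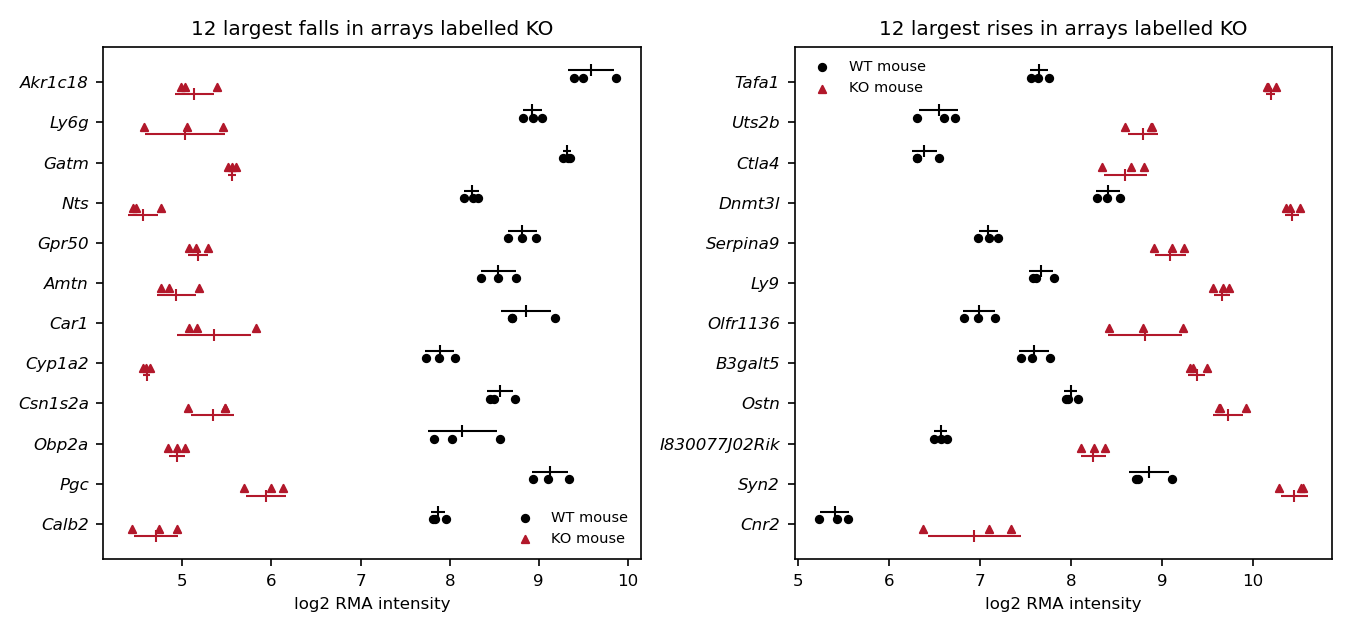
Log2 RMA intensity (horizontal axis) of the 12 genes with the largest fall and the 12 with the largest rise, one point per mouse (circles WT, triangles labelled KO), with the mean (tick) and SD (bar) of each group of 3. Akr1c18 moved from 9.59 to 5.13 and Tafa1 from 7.65 to 10.19 (genes were chosen among those whose groups do not overlap).

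Among 13925 genes tested with limma at a Benjamini-Hochberg adjusted threshold of 0.05, 1963 fell and 1676 rose, so 26.1% of those tested changed. By 2-fold or more, 294 fell and 73 rose. Of the 3639 called genes, 3577 had groups that did not overlap, as did 5909 of all tested genes, a share that chance alone puts at 10% for 3 mice against 3. In 202 of the genes that fell, 112 of them by 2-fold or more, every array labelled KO lay under the intensity filter, so their fold is limited by the background. The count of higher genes was 1052 without KO replicate 1. When the intensity filter was applied again to the 5 arrays left, it was 1012 without KO replicate 1 and 1095 without KO replicate 3, and the falls of 2-fold or more numbered 192 without WT replicate 1 and 169 without WT replicate 3. With limma's treat at a minimum log2 change of 0.5, 338 genes fell and 118 rose.

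**Figure D3:**
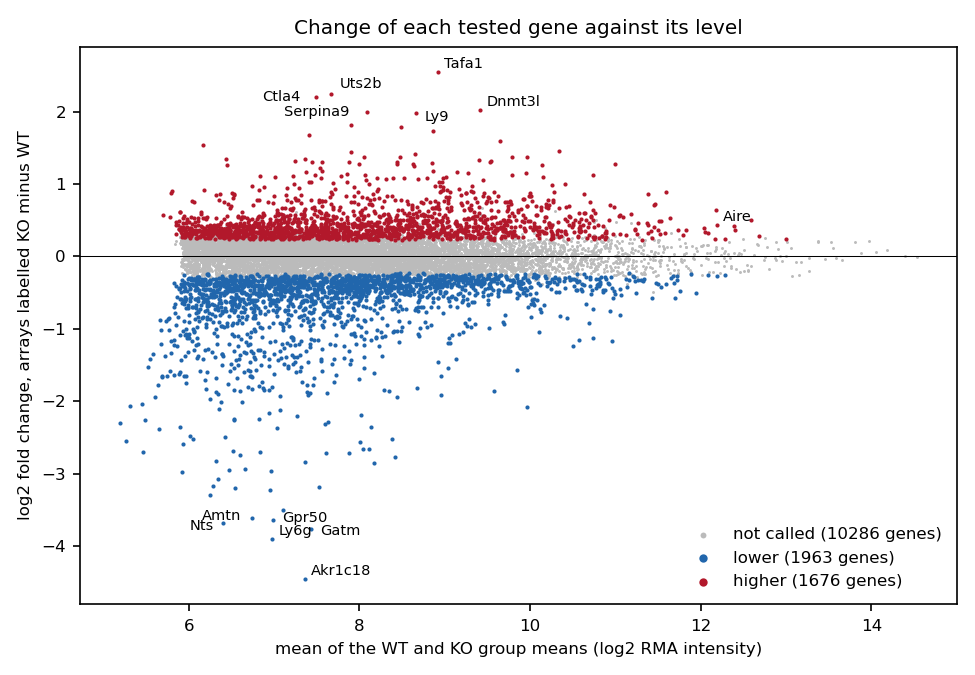
Log2 fold change (labelled KO minus WT, vertical axis) of 13925 tested genes against the mean of both groups (log2 RMA intensity), with 1963 lower genes in blue, 1676 higher genes in red and 10286 others in grey. Falls reach -4.45 (Akr1c18) and rises 2.54 (Tafa1).

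Known Aire-dependent antigens, genes of other organs that medullary cells express with Aire, were mostly lower among those bright enough to test. Of 13 tested, 12 fell and 0 rose by limma (12 and 0 adjusted over the list alone), with a median log2 change of -1.84. Cyp1a2 fell from 7.89 ± 0.16 to 4.60 ± 0.04, the Purkinje cell protein gene Pcp4 from 9.81 ± 0.14 to 7.03 ± 0.29 and the salivary gene Mucl2 from 7.88 ± 0.40 to 4.81 ± 0.10 (SD, n = 3). The hormone gene Sst fell by 1.84 on the log2 scale, Tff3 by 1.58 and S100a8 by 1.94. Ins2, the insulin gene, was not called at -0.18. Another 7 were too dim to test, among them Muc6 (0.04) and Rbp3 (-0.03), and with no intensity filter the median was -1.15. Cyp1a2, Csn1s2a, Csn1s1, Mucl2, Dcpp1 and Bpifb9a passed the filter on WT arrays alone. Camera gave adjusted p = 6.8e-15 for the list, and adjusted p = 0.073 with an estimated correlation. The list was written from general knowledge of Aire, which can rest on arrays like these, so it is not independent evidence of the direction.

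In the casein and enamel gene cluster, 3 of 4 tested genes fell and 0 rose (3 and 0 adjusted over the list alone). Amtn fell from 8.54 ± 0.19 to 4.93 ± 0.22, Csn1s2a from 8.56 ± 0.15 to 5.34 ± 0.24 and Csn1s1 from 6.34 ± 0.36 to 4.28 ± 0.12 (SD, n = 3), while Csn2 was at 0.19 and not called. The median was -2.64 (camera adjusted p = 0.00024, and adjusted p = 0.11 with an estimated correlation). Another 10 cluster genes were too dim to test, and with no intensity filter the median was -0.50. Amtn, Csn1s2a and Csn1s1 passed the filter on WT arrays alone and could only fall. The share that fell, the median and the camera result therefore lean on the filter. Csn1s1 and Csn1s2a also stand among the Aire-dependent antigens.

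Antigens reported to be expressed without Aire moved in both directions. Of 14 tested, 6 fell and 2 rose (6 and 2 adjusted over the list alone), with a median of -0.23. The fibrinogen gene Fgb fell 3.40-fold, the epidermal keratin gene Krt10 3.62-fold and the apolipoprotein gene Apob 2.36-fold, and the monoamine oxidase gene Maoa rose 2.44-fold from 8.21 ± 0.10 to 9.50 ± 0.03 (SD, n = 3). Gad1, at -0.23, was not called. Fgb passed the intensity filter on WT arrays alone and could only fall. Camera gave adjusted p = 0.0087, and adjusted p = 0.18 with an estimated correlation. The call was also lost with the stricter intensity filter (adjusted p = 0.35) and, with the filter applied again, without WT replicate 3 (adjusted p = 0.051).

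Enterohepatic genes, those of liver and intestine, fell as a group: 11 of 16 tested fell and 0 rose by limma (12 and 1 adjusted over the list alone). Apoa1 fell 5.72-fold from 9.64 ± 0.30 to 7.13 ± 0.11 (SD, n = 3), fibrinogen Fgg 5.66-fold, albumin (Alb) 4.02-fold and Fgb 3.40-fold. The transcription factor genes Hnf4a, at -0.19, and Hnf4g, at 0.29, were not called, and Cdx2 fell by 0.43. The list median was -1.06 (camera adjusted p = 1.9e-10, and adjusted p = 0.044 with an estimated correlation). With the filter applied again, it was -0.42 without WT replicate 1, -0.46 without WT replicate 2 and -0.49 without WT replicate 3, and with no intensity filter -0.48. Fgg, Alb and Fgb passed the filter on WT arrays alone and could only fall, so the counts and the median lean on the filter.

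Keratinocyte differentiation genes, which build the outer layers of skin, fell in 19 of 27 tested and rose in 1 (20 and 1 adjusted over the list alone). The keratin gene Krt1 fell 6.35-fold from 9.38 ± 0.28 to 6.71 ± 0.26, the kallikrein protease gene Klk5 4.76-fold from 7.66 ± 0.24 to 5.41 ± 0.14, Krt77 3.78-fold and Klk7 2.90-fold (SD, n = 3). Involucrin (Ivl) fell by 0.91 on the log2 scale and loricrin (Lor) by 0.58. Grhl3, a transcription factor of epidermal differentiation, rose by 0.32. The median was -0.58 (camera adjusted p = 7.9e-11, and adjusted p = 0.044 with an estimated correlation).

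Of the 17 tested neuroendocrine genes, 10 fell and 2 rose (10 and 2 adjusted over the list alone), and those with the largest falls encode secreted peptides. Nts fell from 8.25 ± 0.08 to 4.56 ± 0.17, peptide YY (Pyy) 5.91-fold from 9.29 ± 0.03 to 6.73 ± 0.04, cholecystokinin (Cck) 2.50-fold and Gip 2.44-fold (SD, n = 3). Nts passed the intensity filter on WT arrays alone and could only fall. The transcription factor gene Insm1 and the synaptic vesicle gene Syp rose by 0.40 and 0.30, and chromogranin Chga, at 0.20, was not called. The median was -0.42 (camera adjusted p = 9.7e-05, and adjusted p = 0.073 with an estimated correlation). It was -0.24 without WT replicate 3 with the filter applied again, -0.09 with no intensity filter and -0.82 with the stricter one.

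Microfold cell genes, named for the antigen-sampling cells of the gut epithelium, fell in 8 of 14 tested and rose in 1 (9 and 1 adjusted over the list alone). Gp2, an uptake receptor for bacteria, fell 4.59-fold from 8.36 ± 0.37 to 6.16 ± 0.10, Ccl20 2.68-fold, Ccl9 2.58-fold and Prg3 1.60-fold (SD, n = 3). Spib and Sox8, transcription factor genes of these cells, stood at 0.03 and 0.11 and were not called, and Tnfrsf11b rose by 0.35. The median was -0.37 (camera adjusted p = 0.00021, and adjusted p = 0.11 with an estimated correlation).

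Muscle genes fell in 8 of 18 tested and rose in 1 (9 and 2 adjusted over the list alone). Embryonic myosin Myh3 fell 3.01-fold, cardiac actin Actc1 2.14-fold and troponin Tnni1 1.86-fold, and desmin (Des) rose 2.18-fold from 9.22 ± 0.06 to 10.35 ± 0.04 (SD, n = 3). The myogenic regulator genes Myog, at 0.27, and Myod1, at 0.02, were not called. Myh3 passed the intensity filter on WT arrays alone and could only fall. The median was -0.24 (camera adjusted p = 0.0089, and adjusted p = 0.28 with an estimated correlation). The call was also lost with the stricter intensity filter (adjusted p = 0.096) and, with the filter applied again, without WT replicate 1 (median -0.12, 0.089) or WT replicate 2 (0.054). In the same fits the median was -0.15 without WT replicate 3.

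Tuft and ciliated cell genes showed no shift as groups by camera at the reported settings. Of 18 tuft cell genes, 1 fell and 2 rose (1 and 1 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.68), which was -0.01 without KO replicate 1 and -0.14 without KO replicate 3. Dclk1 fell 1.53-fold and the homeobox gene Hmx3 rose 1.49-fold, while the tuft cell regulator Pou2f3 stood at -0.14 and was not called. Tas1r3 rose 1.28-fold with overlapping groups, and lost its call without WT replicate 1 (0.33, limma adjusted p = 0.10), WT replicate 3 (0.33, 0.10), KO replicate 2 (0.25, 0.15) or KO replicate 3 (0.32, 0.13), and with all arrays with no intensity filter (0.051) or every probe set on its own (0.099). Of 14 ciliated cell genes, 4 fell and 0 rose (4 and 1 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.27). The ciliated median was -0.10 with no intensity filter (adjusted p = 0.024), -0.03 with another quantile normalization and -0.02 with the stricter filter. It was -0.08 without WT replicate 1, -0.02 without WT replicate 3, -0.09 without KO replicate 2 and -0.02 without KO replicate 3, and, with the filter applied again, -0.01 without WT replicate 2. Fam183b fell by 0.90, Tppp3 by 0.50, Rfx3 by 0.34 and Dnah5 by 0.31, and the ciliogenesis regulator Foxj1, at 0.01, was not called. Rfx3 lost its call without KO replicate 1 (limma adjusted p = 0.065), and Dnah5 without WT replicate 2 (0.078), KO replicate 2 (0.051) or KO replicate 3 (0.10).

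Some genes of antigen presentation and costimulation rose in the mice labelled KO. The MHC class II genes H2-Ob and H2-Oa, which restrain peptide loading, rose 1.78-fold from 9.58 ± 0.12 to 10.41 ± 0.01 and 1.52-fold from 10.34 ± 0.08 to 10.95 ± 0.16 (SD, n = 3). H2-DMa rose 1.43-fold, the protease gene Ctss 1.38-fold and the class II transactivator Ciita by 0.29 on the log2 scale, and Lgmn fell by 0.32. The genes of the classical class II chains, H2-Aa, H2-Ab1 and H2-Eb1, stood at 0.20, 0.20 and 0.22 and were not called. In this list 5 of 11 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0041, and adjusted p = 0.25 with an estimated correlation). Among 10 costimulation and checkpoint ligands, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0021, and adjusted p = 0.11 with an estimated correlation). Cd86 rose 1.95-fold from 8.50 ± 0.07 to 9.46 ± 0.10, Cd70 1.55-fold, Pdcd1lg2 1.43-fold and Icosl, next to Aire, 1.35-fold. Cd80, at 0.22, was not called.

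Chemokine and cytokine genes fell in 8 of 17 tested and rose in 2 (9 and 2 adjusted over the list alone). Ccl5 fell 2.98-fold from 10.63 ± 0.13 to 9.06 ± 0.05, Ccl20 2.68-fold and Ccl9 2.58-fold, and Ccl22 and Ccl17, ligands of Ccr4, fell by 1.19 and 0.65 on the log2 scale. Il15, a cytokine for natural killer and memory T cells, rose 2.51-fold from 8.74 ± 0.07 to 10.06 ± 0.05 (SD, n = 3), and Ccl25 rose by 0.49. The median was -0.28 (camera adjusted p = 0.0018, and adjusted p = 0.094 with an estimated correlation), and the call was lost when every probe set was tested on its own (median -0.12, adjusted p = 0.055).

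Of 19 genes of medullary epithelial identity, 7 fell and 1 rose (7 and 1 adjusted over the list alone). Krt19 fell 3.62-fold from 9.28 ± 0.05 to 7.42 ± 0.19, Krt5 1.80-fold and Cdh1 1.30-fold, while Relb, a transcription factor of medullary development, rose 1.28-fold (SD, n = 3). The regulator Fezf2 stood at -0.21 and was not called. The median of -0.18, which was -0.12 without KO replicate 1, did not pass camera (adjusted p = 0.056, and adjusted p = 0.28 with an estimated correlation). It passed without WT replicate 1 (adjusted p = 0.031) or KO replicate 3 (0.027), with no intensity filter (0.021), with arrays centred on their median (0.0496) and with an offset of 32 before the log (0.049).

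Of 19 tested interferon response genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 1.7e-05, and adjusted p = 0.11 with an estimated correlation). Rsad2 fell 3.21-fold from 8.31 ± 0.05 to 6.63 ± 0.20, Ifit2 3.26-fold, Gbp3 2.24-fold and the chemokine gene Cxcl9 1.89-fold (SD, n = 3). Psmb9 rose by 0.26, and Irf1, at -0.06, was not called. Ifit2 passed the intensity filter on WT arrays alone and could only fall. Dissociation and stress response genes, which cell preparation can induce, fell in 10 of 18 and rose in 0 (11 and 0 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 9.7e-05, and adjusted p = 0.094 with an estimated correlation). Nr4a1 fell 1.70-fold, Atf3 1.48-fold, Fos 1.42-fold and Ier3 1.36-fold, and the heat shock gene Hspa8, at -0.04, was not called. These falls in handling-related genes accompanied the falls in the antigen, keratinocyte and interferon lists.

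Cell cycle genes fell in 8 of 24 tested and rose in 0 (8 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0012, and adjusted p = 0.38 with an estimated correlation). The mitotic kinesin Kif11 fell 1.67-fold from 8.30 ± 0.14 to 7.56 ± 0.29, Top2a 1.55-fold, Mki67 1.45-fold and Mcm4 1.25-fold (SD, n = 3). Mcm4 lost its call without WT replicate 1 (limma adjusted p = 0.068) or KO replicate 1 (0.070). Averaged with a dim second probe set, Top2a stood at -0.24 on the log2 scale and was also not called (limma adjusted p = 0.10). Of 13 housekeeping genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.59), which was 0.02 without WT replicate 1, -0.05 without WT replicate 2 and -0.03 without WT replicate 3 or KO replicate 2. That gene, Gusb, fell 1.19-fold (limma adjusted p = 0.036) and was not called without WT replicate 1 (0.057), WT replicate 2 (0.079), WT replicate 3 (0.063), KO replicate 1 (0.12), KO replicate 2 (0.056) or KO replicate 3 (0.098). With all arrays its call was lost with arrays centred on their median (limma adjusted p = 0.059), every probe set on its own (0.054) or the replicate number as a block (0.077).

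Markers of cells that the CD45-negative gate should remove were measured as well. Thymocyte markers fell in 2 of 12 tested and rose in 0 (2 and 0 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.061, and adjusted p = 0.47 with an estimated correlation). Cd3g was 8.18, 8.04 and 9.32 in WT and 7.08, 7.68 and 6.59 in the mice labelled KO, and Ptprc, the CD45 gene, fell 1.54-fold. The 12 markers lay a median 0.62 higher in WT replicate 3 than in the other WT mice, the array on which the Aire-dependent antigens also lay a median 0.25 higher. Ptprc lost its call without WT replicate 3 (-0.42, limma adjusted p = 0.064) or KO replicate 3 (-0.47, 0.092), and with every probe set on its own (0.077), and Cd3g lost its call with limma's trended, robust variances (0.10). The list median was -0.09 without WT replicate 3 (camera adjusted p = 0.21) and -0.11 with the stricter intensity filter. The list passed camera without WT replicate 1 (adjusted p = 0.023), WT replicate 2 (0.026) or KO replicate 2 (0.022), and with no intensity filter (0.032, median -0.13).

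B cell markers rose in 4 of 6 tested and fell in 0 (5 and 0 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0056, and adjusted p = 0.11 with an estimated correlation). The complement receptor gene Cr2 rose 2.04-fold from 8.42 ± 0.14 to 9.45 ± 0.20 and the kinase gene Blk 1.39-fold (SD, n = 3). Pax5 rose 1.24-fold and Cd79b 1.18-fold. Cd79b was not called without WT replicate 1 (limma adjusted p = 0.097), WT replicate 2 (0.11), KO replicate 1 (0.12), KO replicate 2 (0.064) or KO replicate 3 (0.11), nor with all arrays with no intensity filter (0.053), with every probe set on its own (0.055) or with the replicate number as a block (0.090). Pax5 was not called without WT replicate 1 (limma adjusted p = 0.10), WT replicate 3 (0.065), KO replicate 1 (0.13) or KO replicate 2 (0.078), nor with every probe set on its own (0.068). With no intensity filter the list was not called (median 0.13, camera adjusted p = 0.27), and with the stricter one its median was 0.47. Another 5 markers, Ighm and Ms4a1 among them, were too dim to test.

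Dendritic cell and macrophage markers moved apart. Of 14 tested, 4 fell and 5 rose (6 and 5 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.49), which was 0.32 with the stricter intensity filter and -0.07 with none. With the filter applied again it was -0.09 without WT replicate 1 and -0.01 without WT replicate 3. The macrophage gene Adgre1 fell 2.99-fold from 6.92 ± 0.10 to 5.34 ± 0.04 and the integrin gene Itgam 2.45-fold, while the Fc receptor chain gene Fcer1g rose 2.60-fold from 7.79 ± 0.11 to 9.17 ± 0.21 and Irf8 1.68-fold (SD, n = 3). Adgre1 and Itgam passed the filter on WT arrays alone and could only fall, so the count of falls and the median lean on the filter. Cortical epithelial markers moved in both directions as well: 2 of 10 fell and 5 rose (2 and 5 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.37). That median was 0.07 with no intensity filter, 0.16 with another quantile normalization, 0.17 with arrays centred on their median and 0.16 with every probe set on its own. Enpep, which encodes the Ly51 antigen used in the sort, fell 1.99-fold from 7.26 ± 0.01 to 6.27 ± 0.10, and Ctsl fell 1.65-fold. Cd83 rose 1.64-fold and Tbata 1.42-fold, and Psmb11 was too dim to test.

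Among fibroblast markers, 3 of 11 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.079, and adjusted p = 0.41 with an estimated correlation). Sparc fell 2.70-fold, Mfap5 1.66-fold and Col1a1 1.55-fold, and decorin (Dcn) rose 1.68-fold. The list passed camera without KO replicate 2 (adjusted p = 0.042), with array weights (0.048) and, with the filter applied again, without WT replicate 3 (0.046, median -0.08). With no intensity filter its median was 0.04. Of 9 endothelial markers, 1 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.32), which was -0.06 with no intensity filter. Flt1 fell 1.30-fold but was not called without WT replicate 1 (limma adjusted p = 0.062), KO replicate 2 (0.057) or KO replicate 3 (0.069). Egfl7 rose 1.31-fold but was not called without WT replicate 3 (0.064) or KO replicate 2 (0.071), nor with every probe set on its own (0.060). Of 5 erythroid markers, 3 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.091), which was -0.55 with the stricter intensity filter. Car2, a carbonic anhydrase that many epithelia express, fell 3.46-fold, Epb42 fell 1.47-fold and Slc4a1 1.28-fold. Slc4a1 was not called without WT replicate 1 (limma adjusted p = 0.070), KO replicate 2 (0.051) or KO replicate 3 (0.075).

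Xist, transcribed from the inactive X chromosome, was 11.39, 11.28 and 11.09 in WT and 10.66, 10.79 and 10.75 in the mice labelled KO, a fall of 1.43-fold (limma adjusted p = 0.0020). The Y-linked genes Eif2s3y, Kdm5d and Uty lay between 3.51 and 4.59 on all 6 arrays and were too dim to test.

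**Figure D4:**
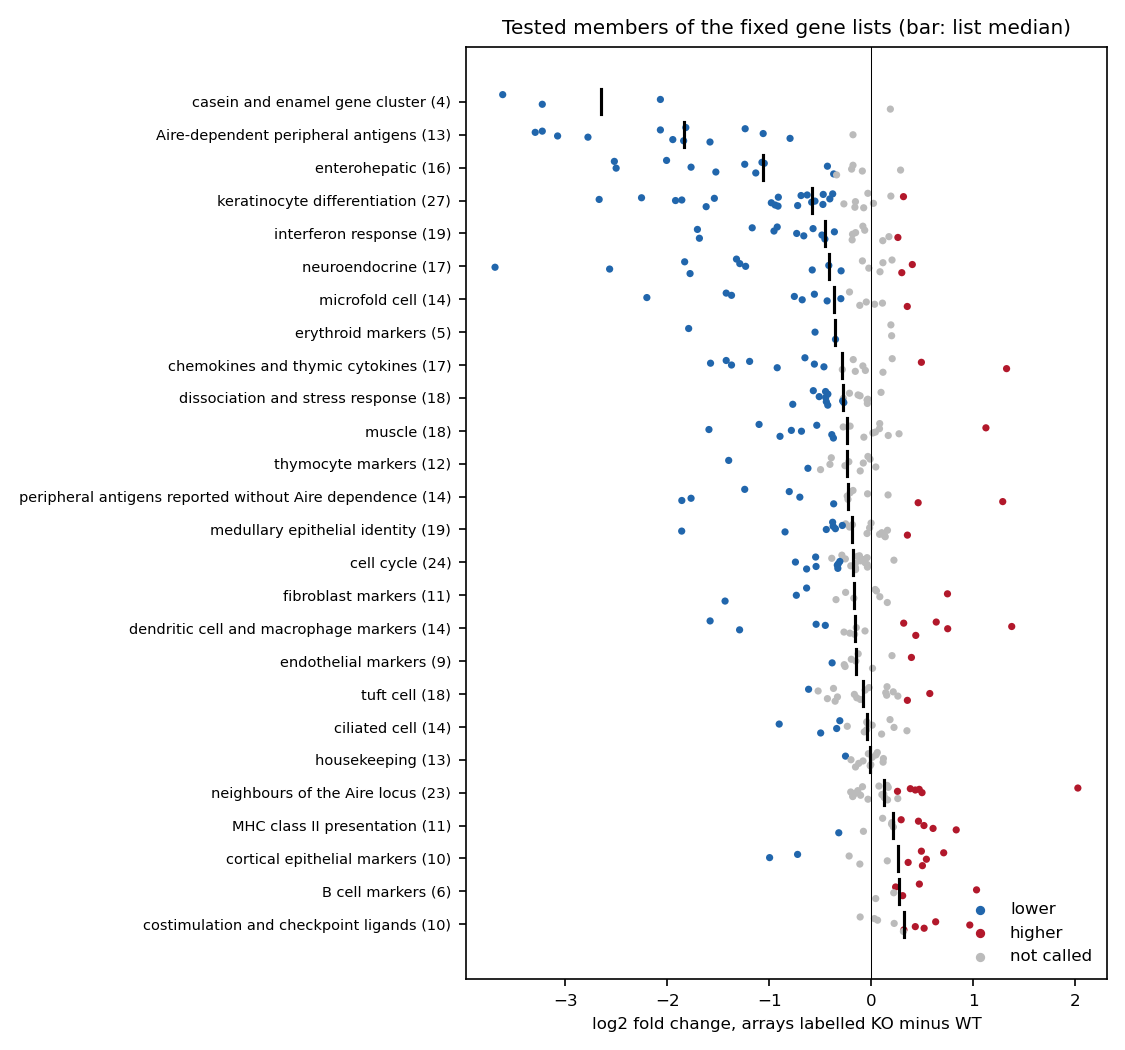
Log2 fold change (labelled KO minus WT, horizontal axis) of each tested member of 26 gene lists, with lower genes in blue, higher genes in red, others in grey and the list median as a bar; the number of tested members stands beside each name. Medians run from -2.64 in the casein and enamel cluster to 0.32 among costimulation and checkpoint ligands.

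Over the 26 lists, camera called 12 lower and 3 higher, and 2 of these calls, keratinocyte differentiation and the enterohepatic list, held with an estimated correlation. The estimate was -0.017 for neuroendocrine genes, -8.2e-05 for chemokines and cytokines and -0.079 for B cell markers, all under the preset 0.01. In the other lists that lost their call it lay above 0.01. A higher correlation between genes therefore does not account for every lost call. Members that passed the intensity filter on WT arrays alone, such as Klk5 and Fgg, could only fall, which favours a lower call of their lists.

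Genes that fell lay next to each other more often than chance placement gives. In gene order, 484 pairs of adjacent tested genes both fell, against 276 expected from permuting the calls (1.75 times, one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Without pairs whose symbols share their first 3 letters, 351 pairs stood against 261 expected (1.35 times, permutation p = 1e-04 with 10000 permutations). In the kallikrein cluster, from Klk14 to Klk1b27, 13 of 15 consecutive tested genes fell, among them Klk5, Klk7 and Klk8. From S100a5 to Lce1h, in the epidermal differentiation cluster, 13 of 15 fell as well, among them S100a8, Lor, Ivl and Sprr3. The highest count in any window was 11 in 200 permutations, which treat genes as independent. Both windows hold members of gene families, which can share probe sequence, and windows were not counted again with families left out.

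Whether the spread between mice differs between the groups could not be settled with 10 splits. The median SD per gene was 0.11 among WT mice and 0.09 among mice labelled KO, and the median log2 ratio of the SDs over 13925 genes was 0.22. An exact permutation over the 10 ways to split the arrays gave a ratio as far from 0 in 6, and the smallest p it allows is 0.1. Every other split mixes the genotypes. For genes that differ between them, both SDs then reflect that difference, which pulls the ratio towards 0. The other splits are therefore a poor comparison, most so for the antigens that fell. For the 13 Aire-dependent antigens, the median log2 ratio was 0.37 (1 of 10 splits as large, which decides nothing for this reason), although the median SD was lower in WT (0.16) than in the mice labelled KO (0.18). That ratio turned to -0.36 with the stricter intensity filter and was 0.65 with none.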

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

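The counts of probe sets without a single symbol, the 3 tests of genes beside Aire, the thymocyte and dendritic cell tests, and the scaling, dynamic range and Aire RNA tests of WT replicate 3 were chosen only after the result was seen, some in place of earlier tests that normalization or marker choice made void. Probe sets outside the gene comparison also gave signals: of 976 tested probe sets with several gene symbols, 74 were lower and 12 higher in the arrays labelled KO, and of 5565 with no symbol, 133 were lower and 58 higher (limma, Benjamini-Hochberg). They are brought up because the report's comparison does not use them.

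Aire and 5 of the 8 tested genes beside it were higher in the arrays labelled KO. A shift of the whole array scale, which would move all genes alike, is argued against: the median change of Aire and its 8 nearest genes was 0.313 above that of the 22 tested genes further out, whose changes had an SD of 0.16. An effect on genes next to the targeted locus may be present, since only 0.539% of windows around other genes held as many higher calls. DNA of another strain kept beside the targeted allele stays open: 0 of the 23 tested neighbours were lower, but strain differences in 6 genes can all go one way, and the labels do not say in which strain the allele was made. An effect of the Aire genotype itself on these genes was not tested apart from these.

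Immune cell genes such as Ctla4, Ly9, Cr2 and Fcer1g were among those higher in the arrays labelled KO, in cells sorted as CD45-negative. RNA carried over from thymocytes is argued against by 0 of 12 tested thymocyte markers being higher. RNA carried over from dendritic cells and macrophages stays open: 5 of 14 tested markers were higher, Fcer1g and Irf8 among them, and 4 lower, with a median change of -0.155. Adgre1 and Itgam, among the lower ones, passed the intensity filter on WT arrays alone and could only fall. With the stricter filter the median was 0.32. RNA carried over from B cells stays open too: 4 of 6 tested markers were higher, while the abundant transcripts Cd79a, Ms4a1 and Ighm lay between 4.72 and 5.88, with a median change of -0.113 (Ms4a1 -0.48), but lie under the intensity filter, where a planned test on them decides nothing. Expression by the epithelial cells themselves may also account for the rises and was not tested apart from these.

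In WT replicate 3, genes that fell by 2-fold or more in a fit without it (275 genes) lay a median 0.153 above the other WT mice, and 83 genes that rose by as much lay 0.126 above. A smaller share of other cells in that sort is argued against, since 0 of 7 lists of other cell types had a median under -0.05, and thymocyte markers lay 0.617 above. The medians of 1000 sets of 275 genes not called reached at most 0.0494 there, and those of 1000 level-matched sets at most 0.0601. Genes not called thus did not share the deviation of the lowered genes. RMA forces all arrays to 1 distribution, which holds such medians near 0. The sets therefore cannot decide on a scaling difference or a wider dynamic range of that array. Over all tested genes, that array had a median absolute log2 difference of 0.1436 from WT replicate 1 and 0.1438 from WT replicate 2. Those 2 replicates differed by 0.0901. The medians of the sets keep the sign and cannot see a deviation in both directions, which stays open for WT replicate 3. A higher level of Aire RNA in that mouse cannot be told apart from no difference, since Aire there was -0.007 from the higher of the other WT arrays. A difference between mice in how many cells express these antigens may remain and was not tested.

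The 6 arrays split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.1. The real split alone gave counts as large for genes lower (1963, 1 of 10 splits), higher (1676, 1 of 10), lower by 2-fold (294, 1 of 10) and higher by 2-fold (73, 1 of 10), and the highest count in any other split was 0. Every other split mixes the genotypes, so the difference between them widens the spread within its groups, and a 0 there decides nothing. For lists, the real 12 lower stood against at most 10 in another split (1 of 10 as many), and the real 3 higher against at most 10 (7 of 10 as many). For the spread between mice, 6 of 10 splits were as far from 0 as the real 0.22, the highest other being 0.367, and those splits mix the genotypes as well.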

How the results depend on the processing

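The fits that leave out 1 array on the genes tested with all 6, the neighbour fits without WT replicate 3 and those of higher genes were chosen only after the result was seen. Of 72 gene counts under the alternatives (the filter-again fits apart), 69 stayed within 1.5 times the reported one. The 3 others were 338 lower and 118 higher with treat at log2 0.5, which asks for a minimum change, and 1052 higher without KO replicate 1. Leaving out 1 array on the genes tested with all 6 gave 1364 to 1877 lower, 1052 to 1547 higher, 275 to 314 lower by 2-fold, 66 to 83 higher by 2-fold, and 12 to 14 lists lower and 3 to 4 higher. With the filter applied again these were 1364 to 1850, 1012 to 1532, 169 to 310, 66 to 83, 11 to 14 and 3 to 4. The low of 169, without WT replicate 3, and 192, without WT replicate 1, follow from the construction: with 2 WT arrays left, a gene needs an array labelled KO above the filter to be tested. The cause of the lower counts without KO replicates 1 and 3 was not tested. With an estimated correlation, camera called 2 lists lower and 0 higher. The SD ratio of the Aire-dependent antigens reversed to -0.36 with the filter at the 60th percentile and moved to 0.65 with none; the cause was not tested. Neighbouring genes lower together stood at 1.35 to 2.02 times the expected pairs over the alternatives, and 1.84 without WT replicate 3. Of 1959 fits of named genes, 1864 held their direction and call, 95 lost the call (47 of them under treat), and 0 reversed. Of list calls, 17 were lost and 11 gained under other settings, 0 and 10 with 1 array left out on the genes tested with all 6, and 3 and 8 with the filter applied again. Replicate numbers do not pair the samples: same-numbered deviations correlated at -0.018, -0.21 and -0.056. With the replicate block, genes lower in Aire KO numbered 1742 and genes higher in Aire KO 1368, with 12 lists lower and 3 higher. The probe set suffix alternative was not run, as the names carry no suffix. Among the limits, 6013 dim genes were not tested.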

Other observations

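The tests of gene families and of higher neighbours were chosen only after the result was seen. Families named by the stem of their symbol, among 226 stems with at least 8 tested genes, were tested for calls in 1 direction, and some of their members also stand in the fixed lists, such as Krt1, Klk5 and Ccl5. Keratin genes (Krt) fell in 27 of 41, among them Krt13 (3.21-fold, limma adjusted p = 2.2e-07) and Krt71 (3.01-fold), and kallikrein genes (Klk) in 15 of 17, among them Klk1b8 (7.71-fold) and Klk1b22 (6.51-fold). Ccl chemokine genes fell in 10 of 15, among them Ccl8 (3.03-fold) and Ccl1 (2.56-fold), and carbonic anhydrase genes (Car) in 8 of 13, among them Car4 (4.87-fold) and Car2 (3.46-fold). Splicing factor genes (Srsf) fell in 6 of 9 by less, Srsf1 by 1.39-fold and Srsf6 by 1.36-fold. Family medians stayed negative under another quantile normalization, centring and an offset of 32, the Srsf median running from -0.31 to -0.29. The hypothesis that families are over-represented among the called genes was met by 5 stems in a one-sided Fisher's exact test with Benjamini-Hochberg adjustment, each among the lower genes. Members of a family can share probe sequence, so they are not independent. Some members, such as Klk5 and Car1, passed the intensity filter on WT arrays alone and could only fall, which favours lower calls of their families. The family counts were not repeated with another filter.

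Higher genes were also neighbours. Adjacent tested genes were both higher in 316 pairs against 200 expected, and in 292 against 189 without pairs of one family. Chance placement of the higher calls is argued against by the one-sided permutation p of 1e-04, the smallest 10000 permutations can give. From Hrc to Plekha4, 12 of 15 consecutive tested genes were higher, Ftl1, Nucb1 and Gys1 among them, against at most 10 in any window of 200 permutations. From H2-DMa to Btnl5-ps, 9 of 15 were higher, H2-Ob and Psmb9 among them, fewer than the 10 that permutations reached. The H2 and Btnl genes of that window belong to families that can share probe sequence. Shared regulation of such stretches may underlie the excess but was not tested. The excess stood at 1.73 times the expected pairs without WT replicate 3.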
